A study of Mus musculus with 19 samples.

How the data were processed

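Gene expression was measured in whole ovaries of CD-1 mice, an outbred strain, at 6 stages: gestation days (gd) 11, 12, 14, 16 and 18 and postnatal day (pnd) 2, with 3 arrays at each stage. Per the labels, mice were mated within a window of 2 hours, and total RNA was amplified in 2 rounds, labelled with biotin and hybridized to Affymetrix Mouse430_2 arrays. The sample labels describe the ovary samples of gd11, gd12 and gd14 as pools of 3 and those of gd16, gd18 and pnd2 as not pooled, whereas the text of the series describes each sample as the ovaries of 1 animal. According to that text each sample came from another dam, except gd11 samples 18 and 19, which shared a dam. The labels give gd11 samples 16 and 18 as gonad with mesonephros and gd11 sample 19 as gonad. A 19th array held RNA of whole animals of both sexes at pnd 0.5 (a pool of 4 males and 4 females) and served as a reference without replicates.

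The deposited values are signal intensities on a linear scale, made by the authors with GCOS per the submitters' processing notes, and scaled so that the 2%-trimmed mean of each array is 500. The version and settings of GCOS and its handling of background are not given in the sources used here. Values ran from 0.07 to 90180.45 over 45101 probe sets, and the trimmed means of the 18 ovary arrays deviated from their mean by at most 5.12e-05 percent. This was within the preset tolerance of 10%, so the values were used as deposited. The depth of an array has no count, and the number of arrays limits the precision.

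Values were transformed to log2(signal + 31), where 31 is the 25th percentile of all values of the ovary arrays. Log2 changes are on this scale, which understates changes of genes with low signal. A probe set was tested when its mean signal in at least 1 stage was above 116.05, the median of all values. This left 26431 probe sets, of which 22163 were annotated to a single gene, for 12592 genes. For a gene with several such probe sets the one with the highest mean represented the gene. Of all probe sets, 34958 were annotated to 1 gene, 932 to several and 9211 to none, and 64 control probe sets were left out. Chromosomes were taken from the mouse annotation of build GRCm38.p6 and were used only to part X-linked from autosomal genes.

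Stages were compared with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8), with 1 term per stage for the 18 ovary arrays, a mean-variance trend and empirical Bayes moderation (12 residual degrees of freedom). The spread was shared by all stages, pooled samples and samples of single animals alike. Each stage was compared with the stage before it, and pnd2 with gd11, and an F test asked for any change over the 6 stages. Tests were two-sided, and p values were adjusted over the 26431 probe sets (Benjamini-Hochberg); a probe set or gene was called at an adjusted p under 0.05. Gene lists were fixed by name in advance and tested with camera from limma, with a preset correlation between genes of 0.01, over the lists with at least 5 tested members. Beside each list stand the adjusted p with an estimated correlation and the number of members called when p values were adjusted over the list alone. The reference array was set beside the mean of the pnd2 arrays without a test.

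The genes named were chosen by a preset rule. For each comparison it took the 6 largest rises and the 6 largest falls among called genes whose 3 arrays of 1 stage all lay above the 3 of the other, leaving out genes known only by a clone or predicted name. It added the called members of each list by size of change: up to 4 in the direction of a called list and 1 against it, and up to 2 of any other list. It also named a panel of marker genes followed through all stages, the genes of a check of sex, and for the reference the 8 highest and 8 lowest ratios. Of the list members given by the rule, the text mostly takes those whose call held under every alternative in which they were tested. This choice was made after the alternatives were seen.

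The gene lists, the rule for named genes, the tolerance and the following alternatives were fixed before the data were examined: a pseudocount of 8 or 116, quantile normalization or median scaling, no filter or a filter at 507.26 (the 75th percentile), a fit to only the arrays compared, no mean-variance trend, array quality weights, gd11 samples 18 and 19 averaged, an added threshold of 2-fold, the mean of all probe sets of a gene, and leaving out each array in turn. Counts of list members without gd11 sample 16 or without gd16 sample 7, the direct comparison of gd18 with gd14, the shares of X-linked genes and the counts of 2 gene families were chosen after the data were seen. Counts of list members without other arrays are not given here. Leaving out any array lowered the number of called probe sets in each comparison, so a lower count does not by itself single out the array left out. The procedure was tested on simulated arrays. The simulation held all 18 ovary arrays. At every stage after gd11, 50 probe sets each were shifted by log2 changes of 0.585, 1, 2 and 3. In the comparison of gd12 with gd11, with the spread taken from all 18 arrays, 20%, 56%, 96% and 96% were recovered. There were 7 false calls among 141 in all. Noise was drawn independently for each probe set, and far fewer probe sets changed than were called in the data. These rates therefore do not give the power or the error of the real comparisons. Numbers were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9. Of 407 list entries 370 were on the array under the symbol used, and the others were not analysed here.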

Results

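The series asked how gene expression in the mouse ovary changes from stage to stage during development. It held 18 ovary arrays, 3 at each of gd11, gd12, gd14, gd16, gd18 and pnd2, and 1 array of whole animals at pnd 0.5. Signals below are means ± SD of the 3 arrays of a stage, and log2 changes are given ± SE of the limma fit. The share of probe sets with a signal above 116.05 ran from 47.85% to 54.17% per array, and the median signal from 102.94 to 137.56. The highest signal of an array was at least 67575 at gd16 and ran from 40789 to 54587 at the other stages. The mean correlation of an array with the others of its stage was 0.9528 to 0.9567 at gd16 and 0.9675 to 0.9778 at the other stages. The ratio of 3' to 5' signal of Gapdh, a sign of RNA quality, moved with stage: 2.987 to 3.28 on the gd11 arrays, 3.479 to 4.284 at gd12, 4.092 to 4.963 at gd14, 4.275 to 5.592 at gd16, 4.85 to 5.204 at gd18 and 5.068 to 5.408 at pnd2. That of beta-actin was 1.766 to 2.262 at gd11, 2.263 to 2.326 at gd12 and 2.431 to 2.829 at gd14. It was 2.331 to 3.538 at gd16, 2.679 to 2.987 at gd18 and 2.084 to 3.361 at pnd2. The median SD of a probe set within a stage was 0.20 to 0.21 on the log2 scale at the stages labelled as pools (gd11, gd12 and gd14) and 0.21 to 0.25 at those labelled as not pooled.

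Over the 6 stages, 16599 of 26431 probe sets (62.8%) and 8577 of 12592 genes changed by the F test of limma. With the filter at the 75th percentile, which tests fewer probe sets, 10897 changed. The stage with the highest mean was pnd2 for 2180 of these genes, gd11 for 1915, gd16 for 1731, gd14 for 1186, gd18 for 800 and gd12 for 765. The first 3 principal components of the ovary arrays held 40.2%, 18.1% and 8.5% of the variance.

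**Figure D1:**
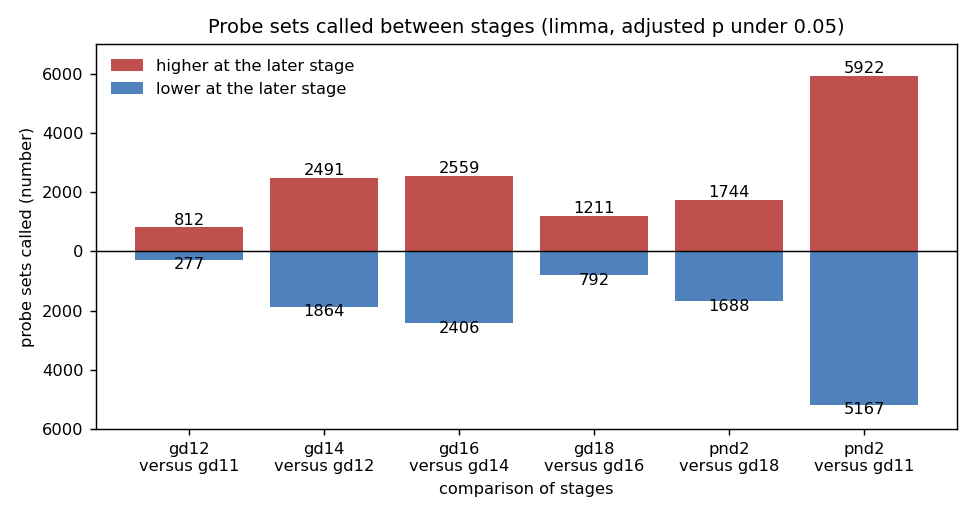
Bars give the number of called probe sets (limma, adjusted p under 0.05) that were higher or lower at the later stage of each comparison. The numbers of called probe sets ran from 1089 (gd12 against gd11) to 4965 (gd16 against gd14) between neighbouring stages.

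From gd11 to gd12, when primordial germ cells settle in the gonad, 3 of the 6 largest rises named were those of genes of germ cell identity and the piRNA pathway (Dazl, Ddx4 and Mael). Dazl, a germ cell RNA-binding protein, rose from 280.3 ± 175 to 3075 ± 1830 (log2 change 3.31 ± 0.40). The germ cell RNA helicase Ddx4 rose by 2.72 ± 0.38 (3.31 without gd12 sample 15), the piRNA factor Mael by 2.53 ± 0.34 and Tex14, a protein of the bridges between germ cells, by 2.42 ± 0.31. Pnliprp1, a lipase-related protein, rose from 42.98 ± 27.4 to 403.5 ± 204 and Dcaf12l1, a WD-repeat protein, from 527.5 ± 52.8 to 3360 ± 2220. The largest falls were those of the arginase Arg1, from 503.5 ± 160 to 30.61 ± 21.9 (-3.14 ± 0.42), the collagen Col8a1 (-2.85 ± 0.44, and -2.24 without gd11 sample 18) and the LIM homeobox factor Isl1 (-2.82 ± 0.55). Protocadherin Pcdh8 (-2.50 ± 0.40), the neural adhesion molecule Chl1 (-2.42 ± 0.42, and -1.75 without gd11 sample 16) and the receptor Megf10 (-2.41 ± 0.40) fell too. Isl1 was not called when only the arrays of both stages were fitted, and its change was -3.68 without gd12 sample 13 and -2.20 without gd12 sample 15. Adjusted p values of these 12 genes ran from 0.000186 (Dazl) to 0.00616 (Isl1). The rule that picked them, here and in each comparison, asked that the 3 arrays of 1 stage lie above the 3 of the other, an order that chance gives for 10% of genes.

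Of 19 tested genes of pluripotency and primordial germ cells, 14 rose and none fell (16 adjusted over the list alone, median 1.41, camera adjusted p = 5.31e-17, adjusted p = 0.0364 with an estimated correlation). Dppa5a, a marker of pluripotent and germ cells, rose from 2815 ± 411 to 9956 ± 3100. Without gd11 sample 16, 9 of the 19 rose. Without any 1 array of this comparison, called probe sets numbered 339 to 894, against 1089 with all. Such drops in the members called therefore need not be particular to that sample. Of 18 genes of germ cell identity and the piRNA pathway, 9 rose (13 adjusted over the list alone, median 1.18, adjusted p = 1.21e-15, and adjusted p = 0.0564 with an estimated correlation), among them the germ cell ADP/ATP carrier Slc25a31 (2.28 ± 0.34). Of 30 genes of meiotic prophase 9 rose (15 adjusted over the list alone, 5 without gd11 sample 16, median 0.70, adjusted p = 3.15e-08, and adjusted p = 0.161 with an estimated correlation). Sycp3, of the axis of meiotic chromosomes, rose from 65.97 ± 17.1 to 419.3 ± 282. The recombination factor Tex15 and the synaptonemal complex protein Syce1 rose by 1.56 ± 0.28 and 1.55 ± 0.27. Of 24 genes of oocytes and primordial follicles 5 rose and 1 fell (6 and 1 adjusted over the list alone, 3 and 0 without gd11 sample 16, median 0.22, adjusted p = 0.00752, adjusted p = 0.369 with an estimated correlation, and 0.0597 in a fit of the compared arrays). The germ cell factor Sohlh2 rose from 166.5 ± 23.6 to 668.6 ± 262.

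In the supporting lineage, 10 of 21 granulosa lineage genes rose and none fell (16 and 1 adjusted over the list alone, median 0.91, adjusted p = 1.22e-10, and adjusted p = 0.0685 with an estimated correlation). The activin antagonist Fst rose from 710.7 ± 82.0 to 3633 ± 2670 (2.07 ± 0.31), and Amhr2, the receptor of anti-Müllerian hormone, from 2069 ± 451 to 6815 ± 2820 (1.63 ± 0.24). Of 15 Wnt pathway genes 3 rose (7 adjusted over the list alone, median 0.43, adjusted p = 0.0011, and adjusted p = 0.13 with an estimated correlation), including the Wnt target Sp5 (1.87 ± 0.29) and the ligand Wnt5a (1.20 ± 0.23). Hox genes, which pattern the body axis, were called lower: 3 of 16 fell (9 adjusted over the list alone, 2 without gd11 sample 16, median -0.94, adjusted p = 1.16e-05, and adjusted p = 0.161 with an estimated correlation), with Hoxa7 at 220.2 ± 17.2 and then 22.92 ± 16.5. Of 16 genes of cholesterol synthesis 4 fell (10 adjusted over the list alone, 1 without gd11 sample 16, median -0.43, adjusted p = 2.22e-08, and adjusted p = 0.0656 with an estimated correlation), including the enzyme Hsd17b7 (-0.85 ± 0.17). Cell cycle genes were called lower as a list (median -0.19, adjusted p = 0.00106, and adjusted p = 0.359 with an estimated correlation). By limma 0 of the 28 members were called on either adjustment and 7 were at an unadjusted p under 0.05. The nervous tissue list was called lower too (median -1.63, adjusted p = 0.00652, and adjusted p = 0.359 with an estimated correlation). By limma 0 of its 7 members were called on either adjustment and 5 had an unadjusted p under 0.05. The list's adjusted p was 0.257 without gd11 sample 16 and 0.073 with array quality weights. On that array the neuronal gene Stmn2 had a signal of 7965, against 227 and 291 on the other gd11 arrays, and on that of gd12 sample 13 a signal of 744, against 120 and 160 on the other gd12 arrays.

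In all, 1089 probe sets (4.12%) were called, 812 higher and 277 lower at gd12, for 593 genes. The count was 339 without gd12 sample 14, 629 without gd11 sample 16, 533 when only the arrays of both stages were fitted, 687 with gd11 samples 18 and 19 averaged and 545 with an added threshold of 2-fold. After median scaling 626 were higher and 404 lower. The Gapdh and beta-actin 3' to 5' ratios did not overlap between the arrays of both stages. The labels give gd11 samples 16 and 18 as gonad with mesonephros and the gd12 samples as ovary. Stage and the tissue collected therefore cannot be fully told apart in this comparison.

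Between gd12 and gd14, the days of entry into meiosis, genes of meiotic prophase rose most. Of 30 tested genes 26 rose and none fell (27 adjusted over the list alone, median 3.82, camera adjusted p = 1.22e-36, and adjusted p = 0.00713 with an estimated correlation). Stra8, which licenses meiotic entry in response to retinoic acid, rose from 67.92 ± 62.9 to 2990 ± 720 (5.12 ± 0.47), and the meiotic recombinase Dmc1 from 85.35 ± 36.0 to 1561 ± 170 (3.82 ± 0.26). Terb1, which tethers telomeres to the nuclear envelope, rose by 6.11 ± 0.32, and the synaptonemal complex proteins Sycp1 and Tex12 rose by 5.44 ± 0.32 and 5.42 ± 0.24. Meioc, a regulator of meiotic transcripts, rose by 5.89 ± 0.43 (6.49 without gd12 sample 14).

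The other largest rises were those of the transketolase-like enzyme Tktl1, from 60.19 ± 41.4 to 7051 ± 3330, the germ cell surface protein Tex101 (5.87 ± 0.47, and 6.54 without gd12 sample 14), the testis-expressed gene Tex16 (5.49 ± 0.38) and the X-linked homeobox gene Rhox13 (5.45 ± 0.45, and 4.66 without gd12 sample 15). Of 18 genes of germ cell identity and the piRNA pathway 15 rose (17 adjusted over the list alone, median 2.12, adjusted p = 1.2e-17, and adjusted p = 0.0375 with an estimated correlation). Taf7l, a germ cell transcription factor subunit, rose from 147.7 ± 29.9 to 6707 ± 890, and Mael from 288.9 ± 198 to 4374 ± 914. Of 21 granulosa lineage genes 8 rose and 2 fell (9 and 3 adjusted over the list alone, median 0.45, adjusted p = 0.024, adjusted p = 0.444 with an estimated correlation, 0.182 without gd12 sample 13 and 0.0756 in a fit of the compared arrays). Foxl2, a transcription factor of granulosa cells, rose from 371.5 ± 193 to 1186 ± 229, and Lgr5, a receptor of R-spondins, from 260.9 ± 107 to 1524 ± 217. The oocyte list was not called (4 rose and 1 fell of 24, on either adjustment, adjusted p = 0.316), though the oocyte transcription factor Figla rose from 25.83 ± 22.2 to 334.1 ± 65.6.

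Genes of pluripotency and primordial germ cells fell over the same days. Of 19, 11 fell and none rose (13 adjusted over the list alone, median -0.96, adjusted p = 1.17e-06, and adjusted p = 0.172 with an estimated correlation), including L1td1, an RNA-binding protein of embryonic stem cells (-2.19 ± 0.20), and the germ cell factor Tfap2c (-1.96 ± 0.44). Among the largest falls were the lipase-related Pnliprp2, from 2384 ± 982 to 27.63 ± 8.07, the embryonic globin Hbb-bh1 (-4.47 ± 0.36), the epithelial protein Sprr2d (-4.29 ± 0.43), the tight-junction protein Cldn8 (-3.49 ± 0.41), Shisa3 (-3.47 ± 0.52) and Foxd1, a transcription factor of kidney stroma (-3.10 ± 0.33). Adjusted p values of the 12 largest changes ran from 3.05e-10 (Tktl1) to 0.000147 (Shisa3). By that rule the arrays of both stages did not overlap in them.

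Several lists of somatic genes were called lower at gd14. Hox genes fell in 8 of 16 (13 adjusted over the list alone, median -1.18, adjusted p = 4.32e-07, and adjusted p = 0.172 with an estimated correlation), with Hoxa9 at 5184 ± 2910 and then 747.2 ± 93.1. Endothelial genes fell in 6 of 15 (11 adjusted over the list alone, median -0.67, adjusted p = 2.88e-05, and adjusted p = 0.332 with an estimated correlation), among them Plvap, of the diaphragms of capillaries (-1.60 ± 0.27). Of 28 cell cycle genes 12 fell and 1 rose (17 and 2 adjusted over the list alone, median -0.42, adjusted p = 4.49e-06, and adjusted p = 0.172 with an estimated correlation). The mitotic enzymes Ube2c (-1.01 ± 0.18) and Aurkb (-0.97 ± 0.18) fell, and Bub1, a kinase of the spindle checkpoint, rose by 1.13 ± 0.17. Mesonephros and nephric duct genes fell in 3 of 10 (5 adjusted over the list alone, median -0.57, adjusted p = 0.0346, adjusted p = 0.172 with an estimated correlation, 0.0501 without gd14 sample 11 and 0.0622 without gd14 sample 12). The nephric duct ligand Wnt9b fell from 133.5 ± 54.8 to 23.7 ± 12.8.

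Imprinted growth genes fell in 4 of 12 (4 adjusted over the list alone, median -0.28, adjusted p = 0.0217, adjusted p = 0.364 with an estimated correlation, and 0.066 without gd14 sample 12). Mest, an imprinted hydrolase, fell by 0.70 on the log2 scale. Apoptosis genes fell in 3 of 10 (3 adjusted over the list alone, median -0.33, adjusted p = 0.0288, adjusted p = 0.172 with an estimated correlation, and 0.0622 without gd14 sample 12). These were Bcl2l11, which promotes apoptosis (-0.80 ± 0.16), Chek2 and Mcl1. The list was not parted into genes that promote and genes that oppose apoptosis. The macrophage list was called lower (median -0.52, adjusted p = 0.0205, and adjusted p = 0.444 with an estimated correlation) with 0 of 12 members called by limma on either adjustment and 6 at an unadjusted p under 0.05. Its adjusted p was 0.082 without gd14 sample 10, 0.0667 without gd12 sample 13 and 0.0555 without gd12 sample 15. In all, 4355 probe sets (16.5%) were called, 2491 higher and 1864 lower at gd14, for 2464 genes. The count was 2702 without gd12 sample 13, 2604 without gd12 sample 15 and 1643 with an added threshold of 2-fold. The beta-actin 3' to 5' ratios did not overlap between the arrays of both stages, while those of Gapdh did.

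By gd16 most of the tested genes of meiotic prophase were lower than at gd14. Stra8 fell from 2990 ± 720 to 70.11 ± 43.4 (-4.98 ± 0.47), the meiotic cohesin Rec8 from 1337 ± 426 to 205.1 ± 80.8 and Dmc1 from 1561 ± 170 to 561.5 ± 13.1. Of 30 genes of meiotic prophase 18 fell and 2 rose (20 and 4 adjusted over the list alone, median -1.22, camera adjusted p = 7.42e-08, and adjusted p = 0.471 with an estimated correlation). Without gd16 sample 7, which had a Xist signal of 44.79, 15 fell and 1 rose. Of 19 genes of pluripotency and primordial germ cells 9 fell and none rose (12 and 1 adjusted over the list alone, median -0.87, adjusted p = 1.11e-07, and adjusted p = 0.471 with an estimated correlation). The pluripotency factors Sox2 (-4.05 ± 0.60) and Sall4 (-3.58 ± 0.27) fell, and Lin28a, which blocks let-7 processing, fell from 877.8 ± 450 to 61.67 ± 8.97.

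Other large falls were those of the X-linked homeobox genes Rhox6 (-3.84 ± 0.27) and Rhox9 (-3.30 ± 0.26) and of the embryonic globin Hbb-y, from 32750 ± 1380 to 2508 ± 1090. The largest rise was that of Bzw2, a regulator of translation initiation, from 832.6 ± 714 to 18860 ± 7410 (4.66 ± 0.38, and 5.30 without gd14 sample 10), seen with 1 of its 3 probe sets. The helicase Tdrd9 of the piRNA pathway rose from 389.5 ± 9.69 to 4052 ± 992, the oocyte transcription factors Lhx8 and Sohlh1 by 2.46 ± 0.35 and 2.30 ± 0.30, and the MORN-repeat protein Morn5 by 2.38 ± 0.27. The claudin Cldn13 rose by 2.74 ± 0.52 (3.44 without gd14 sample 11) and the erythroid membrane protein Ermap by 2.57 ± 0.45 (3.20 without gd14 sample 11 and 3.17 without gd16 sample 9). Adjusted p values of the 12 largest changes ran from 1.03e-07 (Hbb-y) to 0.0015 (Cldn13). By that rule the arrays of both stages did not overlap in them.

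Of 18 genes of germ cell identity and the piRNA pathway 9 fell and 2 rose (9 and 2 adjusted over the list alone, 5 and 1 without gd16 sample 7, median -0.71, adjusted p = 0.0347, and adjusted p = 0.937 with an estimated correlation). Rnf17, a Tudor protein of germ cells (-2.11 ± 0.29), and Slc25a31 (-1.62 ± 0.34) fell. The adjusted p of this list was 0.156 without gd16 sample 7, 0.0804 without gd14 sample 10, 0.0824 without gd14 sample 12, 0.0717 after quantile normalization and 0.11 with array quality weights. It was 0.0529 to 0.0759 under 4 further alternatives (pseudocount of 8, median scaling, mean of all probe sets and the filter at the 75th percentile). Cell cycle genes fell in 9 of 28 (9 adjusted over the list alone, median -0.27, adjusted p = 6.65e-05, and adjusted p = 0.543 with an estimated correlation), including Bub1 (-1.56 ± 0.17) and topoisomerase Top2a (-1.05 ± 0.13). Stroma and matrix genes rose in 6 of 17 (9 adjusted over the list alone, median 0.61, adjusted p = 0.0282, and adjusted p = 0.937 with an estimated correlation), among them matrix Gla protein Mgp, from 529.7 ± 88.9 to 1639 ± 297, and the collagen Col1a2 (0.96 ± 0.23). That list's adjusted p was 0.1 without gd16 sample 7, 0.117 without gd16 sample 8, 0.0804 without gd14 sample 10, 0.0834 without gd14 sample 12, 0.118 with array quality weights and 0.053 with the mean of all probe sets.

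Macrophage genes rose in 4 of 12 (7 adjusted over the list alone, 2 of the 13 tested without gd16 sample 7, median 0.78, adjusted p = 0.0207, adjusted p = 0.937 with an estimated correlation, 0.0778 without gd16 sample 8, 0.12 without gd14 sample 10, 0.11 with array quality weights and 0.0551 with the mean of all probe sets). Csf1r, a growth factor receptor of macrophages, rose from 911.1 ± 349 to 1796 ± 305, a call lost without gd16 sample 8, gd14 sample 10 or gd14 sample 12 and with array quality weights. Erythroid genes moved apart: 5 of 9 rose and 2 fell (5 and 3 adjusted over the list alone, 3 and 3 without gd16 sample 7), the list was not called (adjusted p = 0.86), and its median was 1.48 with a mean of 0.28. Granulosa genes rose in 4 and fell in 2 of 21, on either adjustment (adjusted p = 0.725; 3 and 0 without gd16 sample 7), with Foxl2 up from 1186 ± 229 to 2565 ± 161. In all, 4965 probe sets (18.8%) were called, 2559 higher and 2406 lower at gd16, for 2669 genes. The count was 2927 without gd14 sample 12 and 1251 with an added threshold of 2-fold, and 1862 were higher and 2781 lower after median scaling, and 2136 and 2741 after quantile normalization. The step from gd14 to gd16 was also the step from samples labelled as pools to samples labelled as not pooled, so stage and pooling cannot be told apart here.

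From gd16 to gd18, oocyte genes rose. Of 24 genes of oocytes and primordial follicles 12 rose and none fell (13 adjusted over the list alone, 7 without gd16 sample 7, median 1.11, camera adjusted p = 4.18e-09, and adjusted p = 0.0939 with an estimated correlation). Nlrp5, a maternal-effect gene of the oocyte, rose from 139.9 ± 74.0 to 1540 ± 523, Zp2, of the zona pellucida, from 31.85 ± 24.3 to 392.6 ± 150. Kit, the receptor through which oocytes receive Kit ligand, rose from 695 ± 111 to 2989 ± 505. Other large rises were those of Nlrp4f (4.24 ± 0.41, and 4.84 without gd18 sample 6), the scaffold protein Pdzk1 (3.48 ± 0.43), the receptor Gpr143 (2.91 ± 0.37) and Cnpy1 (2.87 ± 0.55, 2.11 without gd16 sample 7 and 3.48 without gd16 sample 8). Trp63, a p53 relative on the apoptosis list, rose from 96.04 ± 39.3 to 1151 ± 409.

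Red cell genes fell over the same days. Of 9 erythroid genes 6 fell and none rose (9 adjusted over the list alone, 4 without gd16 sample 7, median -1.40, adjusted p = 6.14e-09, and adjusted p = 0.0304 with an estimated correlation). Among them were Ermap (-3.31 ± 0.45, and -3.91 without gd16 sample 9), the Rh-associated glycoprotein Rhag (-2.81 ± 0.43), Hbb-y (-2.95 ± 0.26) and the erythroid transcription factor Klf1 (-1.91 ± 0.37). The largest fall was that of Hemgn, a nuclear protein of blood cell precursors, from 1968 ± 403 to 107.8 ± 90.4 (-4.14 ± 0.78, and -3.41 without gd18 sample 5). Cldn13 (-3.05 ± 0.52) and the potassium channel Kcnn4 (-2.79 ± 0.53) fell too. Adjusted p values of the 12 largest changes ran from 6.82e-06 (Trp63 and Hbb-y) to 0.00383 (Cnpy1). By that rule the arrays of both stages did not overlap in them.

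Genes of germ cell identity and the piRNA pathway rose in 5 of 18 (5 adjusted over the list alone, 1 without gd16 sample 7, median 0.62, adjusted p = 5.17e-05, and adjusted p = 0.543 with an estimated correlation). Tdrd9 rose by 0.99 ± 0.24, a call lost without gd18 sample 5 or gd16 sample 7. Cell cycle genes fell in 5 of 28 (8, with 1 rise, adjusted over the list alone, median -0.22, adjusted p = 0.00683, adjusted p = 0.825 with an estimated correlation, and 0.11 without gd16 sample 8), including the replication factor Mcm7 (-0.76 ± 0.11). The pluripotency list was not called (adjusted p = 0.198; 2 of 19 rose, and 4 with 1 fall adjusted over the list alone), while Dppa3, a maternal factor that protects methylation marks, rose from 198 ± 93.8 to 1439 ± 490. In all, 2003 probe sets (7.58%) were called, 1211 higher and 792 lower at gd18, for 1032 genes. The count was 1136 without gd18 sample 4, 1177 without gd18 sample 5, 1156 without gd16 sample 7, 959 when only the arrays of both stages were fitted and 530 with an added threshold of 2-fold.

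From gd18 to pnd2, across birth and the days when primordial follicles form, oocyte genes rose further. Of 24, 16 rose and none fell (18 and 1 adjusted over the list alone, median 2.74, camera adjusted p = 6.09e-22, and adjusted p = 0.00786 with an estimated correlation). Nlrp14 rose from 123.6 ± 69.2 to 8912 ± 1240 (5.94 ± 0.34), Padi6, of the cytoplasmic lattices of the oocyte, from 202.3 ± 88.1 to 10310 ± 2680. The zona pellucida gene Zp3 rose from 115.6 ± 29.5 to 6569 ± 2450. Gdf9, a growth factor that oocytes secrete, rose from 265.7 ± 59.3 to 3376 ± 1400. Also among the largest rises were Oas1c, of the oligoadenylate synthetase family (5.18 ± 0.38), Dcpp1 (5.17 ± 0.36) and Khdc1b (4.88 ± 0.35).

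Genes of meiotic prophase fell in 13 of 30 and rose in 1 (14 and 1 adjusted over the list alone, median -0.60, adjusted p = 1.57e-05, and adjusted p = 0.306 with an estimated correlation). Meioc (-3.28 ± 0.43), the axis protein Sycp2 (-2.28 ± 0.25) and Spo11, which makes the breaks that start meiotic recombination (-2.24 ± 0.33), fell. Of 18 genes of germ cell identity and the piRNA pathway 5 fell and 2 rose (7 and 2 adjusted over the list alone, median -0.61, adjusted p = 0.00204, and adjusted p = 0.429 with an estimated correlation), with Taf7l down from 5422 ± 1580 to 216.9 ± 123 and Tex101 at -3.57 ± 0.47. The other largest falls were those of Tex16 (-3.56 ± 0.38), the meiotic cyclin Ccnb3 (-3.44 ± 0.41) and Rhox13 (-3.34 ± 0.45). Adjusted p values of the 12 largest changes ran from 4.51e-09 (Nlrp14, Padi6 and Zp3) to 8.05e-05 (Rhox13). By that rule the arrays of both stages did not overlap in them.

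Genes of pluripotency and primordial germ cells rose in 7 of 19 (9 adjusted over the list alone, median 0.49, adjusted p = 0.000193, and adjusted p = 0.306 with an estimated correlation). Lin28a rose from 117.3 ± 38.1 to 1074 ± 304, Dppa5a from 1086 ± 157 to 7325 ± 1710 and the pluripotency factor Pou5f1 from 50.42 ± 23.0 to 286.1 ± 47.7. Cell cycle genes rose in 11 of 28 (17 adjusted over the list alone, median 0.47, adjusted p = 4.48e-08, and adjusted p = 0.141 with an estimated correlation), led by Ube2c (2.43 ± 0.18) and the spindle protein Nusap1 (1.23 ± 0.16). Cholesterol synthesis genes rose in 4 of 16 (4 adjusted over the list alone, median 0.28, adjusted p = 0.00357, and adjusted p = 0.306 with an estimated correlation), including squalene synthase Fdft1 (1.18 ± 0.17). The granulosa list was not called (4 rose and 5 fell of 21, on either adjustment, adjusted p = 0.775). Its member Inha, a subunit of inhibin, rose from 1515 ± 290 to 6474 ± 263, and Bmp2 fell from 1432 ± 168 to 350.4 ± 217.

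Imprinted growth genes fell in 6 of 12 (7 adjusted over the list alone, median -0.59, adjusted p = 1.57e-05, and adjusted p = 0.141 with an estimated correlation). Igf2, a growth factor of the fetus, fell from 8026 ± 1420 to 2549 ± 426, and the cell cycle inhibitor Cdkn1c from 7495 ± 1010 to 2713 ± 553. Erythroid genes fell in 4 of 9 (4 adjusted over the list alone, median -0.62, adjusted p = 0.000836, and adjusted p = 0.141 with an estimated correlation), including Slc4a1, the anion exchanger of red cells (-2.93 ± 0.51). Wnt pathway genes fell in 4 of 15 (7 adjusted over the list alone, median -0.51, adjusted p = 0.000836, and adjusted p = 0.141 with an estimated correlation), including Lgr5 (-1.12 ± 0.24). Endothelial genes fell in 3 of 15 (4 adjusted over the list alone, median -0.52, adjusted p = 0.0203, adjusted p = 0.654 with an estimated correlation, 0.142 without pnd2 sample 3, 0.148 without gd18 sample 6 and 0.126 with the filter at the 75th percentile). Hox genes fell in 2 of 16 (2 adjusted over the list alone, median -0.45, adjusted p = 0.0423, and adjusted p = 0.622 with an estimated correlation), with Hoxa5 at -0.80 ± 0.17. That list's adjusted p was 0.0802 without pnd2 sample 1, 0.0841 without pnd2 sample 3, 0.151 without gd18 sample 6 and 0.0515 to 0.0834 under 4 further alternatives (array quality weights, mean of all probe sets, a pseudocount of 116 and the filter at the 75th percentile). In all, 3432 probe sets (13%) were called, 1744 higher and 1688 lower at pnd2, for 1932 genes. After median scaling 2028 were higher and 1327 lower. The count was 1822 without pnd2 sample 1, 2163 without gd18 sample 6 and 1271 with an added threshold of 2-fold.

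Between the ends of the series, gd11 and pnd2, germ cell and granulosa genes rose and embryonic globins fell most. The Gapdh 3' to 5' ratio was also higher on each pnd2 array (5.068 to 5.408) than on each gd11 array (2.987 to 3.28). Of 24 oocyte genes 23 rose (23 adjusted over the list alone, median 4.64, camera adjusted p = 3.8e-18, and adjusted p = 0.0171 with an estimated correlation). Nlrp5 was up from 15.19 ± 11.2 to 19370 ± 1960 (8.74 ± 0.32), Nlrp14 by 7.79 ± 0.34, Padi6 by 7.61 ± 0.31 and Lhx8 by 7.46 ± 0.35. Of 18 genes of germ cell identity and the piRNA pathway 16 rose (16 adjusted over the list alone, median 3.45, adjusted p = 8.33e-11, and adjusted p = 0.0858 with an estimated correlation), including Gtsf1, which licenses transposon silencing (8.03 ± 0.39). Nlrp4f, outside these lists, rose by 7.81 ± 0.41. Of 30 genes of meiotic prophase 18 rose (19 adjusted over the list alone, median 2.11, adjusted p = 5.71e-09, and adjusted p = 0.137 with an estimated correlation), with Sycp3 up from 65.97 ± 17.1 to 12430 ± 3630. Of 21 granulosa lineage genes 16 rose and 1 fell (16 and 2 adjusted over the list alone, median 1.60, adjusted p = 1.47e-05, and adjusted p = 0.171 with an estimated correlation). Foxl2 rose by 4.19 ± 0.23 and Inha by 3.61 ± 0.19, and the gonadal factor Lhx9 fell by 1.93 on the log2 scale.

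The largest falls were those of the embryonic globins Hbb-y, from 31780 ± 733 to 11.29 ± 8.22, Hbb-bh1 (-8.14 ± 0.36) and Hba-x (-7.31 ± 0.28), of Asb4 (-5.99 ± 0.28), of Foxd1 (-5.84 ± 0.33) and of Crabp2, which binds retinoic acid (-5.76 ± 0.38). Adjusted p values of the 12 largest changes ran from 1.64e-14 (Hbb-y) to 1.29e-09 (Crabp2). By that rule the arrays of both stages did not overlap in them. Erythroid genes fell in 7 of 9 (8 adjusted over the list alone, median -2.16, adjusted p = 1.61e-06, and adjusted p = 0.0591 with an estimated correlation). Hox genes fell in 15 of 16 (16 adjusted over the list alone, median -2.54, adjusted p = 3.75e-09, and adjusted p = 0.0858 with an estimated correlation), with Hoxa10 at 1231 ± 247 and then 38.67 ± 8.20. Of 28 cell cycle genes 18 fell and 2 rose (20 and 2 adjusted over the list alone, median -0.69, adjusted p = 2.06e-06, and adjusted p = 0.157 with an estimated correlation), including ribonucleotide reductase Rrm2 (-1.85 ± 0.13). Imprinted growth genes fell in 7 of 12 (7 adjusted over the list alone, median -0.51, adjusted p = 0.000148, and adjusted p = 0.159 with an estimated correlation), with Igf2 at -2.42 ± 0.18.

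Endothelial genes fell in 6 of 15 (6 adjusted over the list alone, median -0.77, adjusted p = 0.00267, and adjusted p = 0.422 with an estimated correlation), including Plvap (-2.69 ± 0.27). Cholesterol synthesis genes fell in 9 of 16 and rose in 2 (9 and 2 adjusted over the list alone, median -0.48, adjusted p = 0.0085, and adjusted p = 0.312 with an estimated correlation), including the isomerase Idi1 (-1.84 ± 0.25). Nervous tissue genes fell in 6 of 7 (6 adjusted over the list alone, 4 of the 6 tested without gd11 sample 16, median -3.44, adjusted p = 0.00928, and adjusted p = 0.312 with an estimated correlation), with the neurofilament gene Nefm at 3264 ± 2490 and then 80.27 ± 73.6. Mesonephros and nephric duct genes fell in 6 of 10 and rose in 1 (6 and 1 adjusted over the list alone, median -1.50, adjusted p = 0.011, and adjusted p = 0.099 with an estimated correlation), with the receptor Ret at 419 ± 24.1 and then 32.13 ± 27.1. The pluripotency list was not called (6 rose and 5 fell of 19, on either adjustment, adjusted p = 0.777): Dppa3 rose by 4.36 ± 0.33, and Sox2 fell by 5.28 on the log2 scale (-4.19 without gd11 sample 16 and -5.92 without gd11 sample 18). In all, 11089 probe sets (42%) were called, 5922 higher and 5167 lower at pnd2, for 5903 genes. The balance turned with scaling, to 5142 higher and 6194 lower after median scaling and 5347 and 5731 after quantile normalization. The count was 7355 with the filter at the 75th percentile and 4883 with an added threshold of 2-fold. The gd11 samples were labelled as pools and those of pnd2 as not pooled. Samples 16 and 18 of gd11 were labelled as gonad with mesonephros and the pnd2 samples as ovary. Neither pooling nor the tissue collected can be fully told apart from stage here.

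In every comparison the median, the mean and the test of a called list had the same sign. They differed in sign for lists that were not called: smooth muscle (lower by the test, median 0.22, mean -0.12) and Wnt genes at gd14, Sertoli, mesonephros and Wnt genes at gd16, granulosa, Sertoli, apoptosis and Hox genes at gd18, and apoptosis and Notch genes in pnd2 against gd11. The same held for steroidogenesis, stroma and apoptosis genes in pnd2 against gd18.

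**Figure D2:**
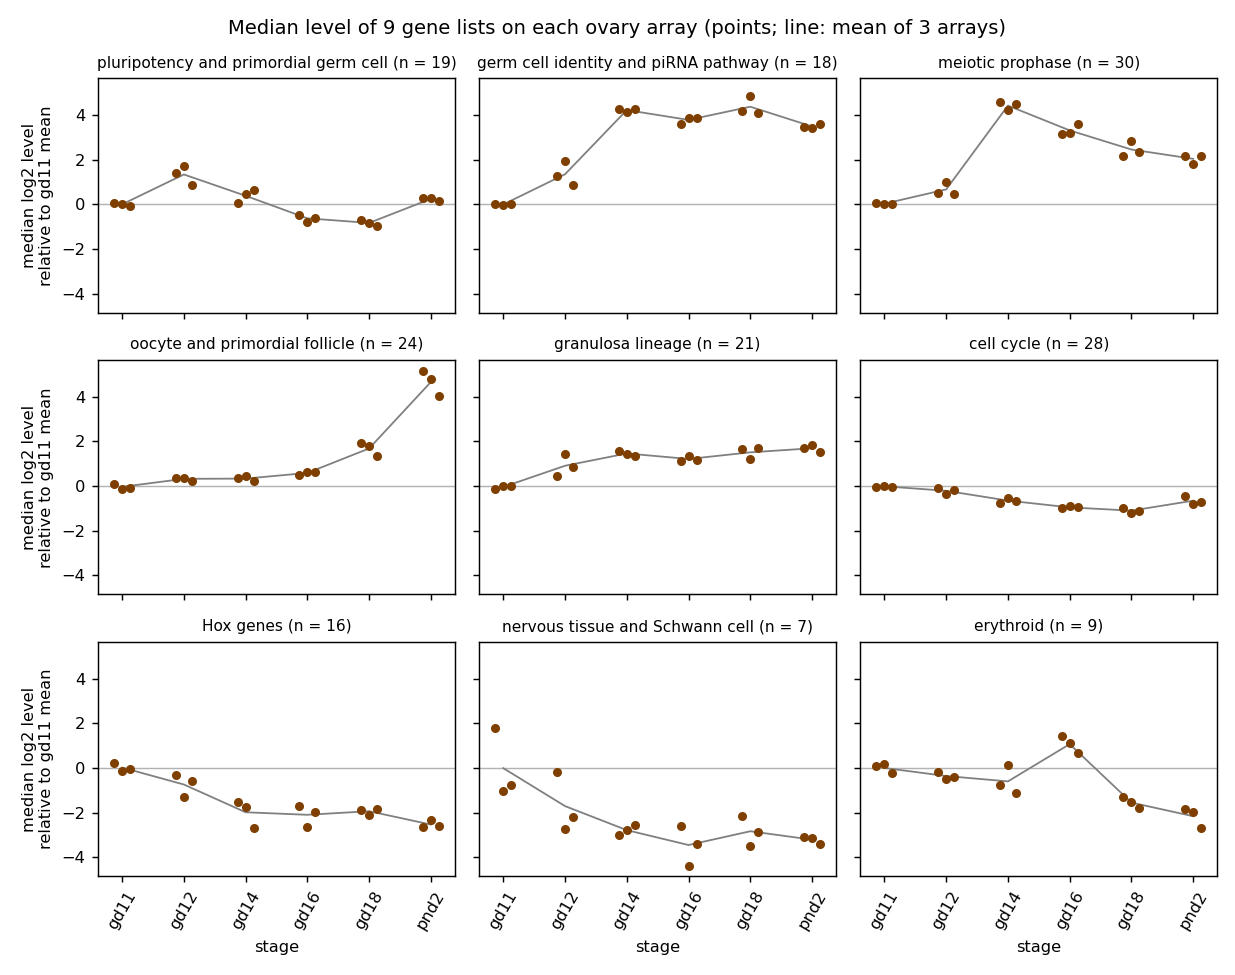
Each panel gives the median log2 signal of the tested genes of 1 list on each ovary array, relative to the gd11 mean, by stage; points are arrays and the line joins the means of 3 arrays. The meiotic list is highest at gd14 and the oocyte list at pnd2.

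Genes of the marker panel followed different courses. Dppa3 had means of 190.9 ± 31.8 at gd11, 678.4 ± 204 at gd12, 198 ± 93.8 at gd16 and 4557 ± 1090 at pnd2. Sycp3 was at 13730 ± 2730 at gd14, 5575 ± 1580 at gd16 and 12520 ± 2090 at gd18; its fall to gd16 (-1.32 ± 0.33) was not called without gd16 sample 7. Nobox, a transcription factor of oocytes, was at 11.24 ± 5.41 at gd14, 209.9 ± 177 at gd16, 697.7 ± 191 at gd18 and 1277 ± 486 at pnd2. Its change to gd16 (2.06 ± 0.51) was 2.98 without gd16 sample 7 and 1.47, no longer called, without gd16 sample 8. That to gd18 (2.02 ± 0.51) was 1.10 without gd16 sample 7, 1.90 without gd18 sample 4 and 1.90 without gd18 sample 5, none of them called, and 2.61 without gd16 sample 8. Neither was called when only the arrays of the compared stages were fitted. Figla rose from 12.22 ± 9.57 at gd11 to 1947 ± 334 at pnd2, and Ddx4 from 187.7 ± 79.0 to 2806 ± 539 with its highest mean at gd14 (8200 ± 1480). Hsd3b1, an enzyme of steroid synthesis, rose from 92.73 ± 3.04 to 1374 ± 795. The proliferation marker Mki67 fell from 8389 ± 654 to 5085 ± 35.2 over the same span (-0.72 ± 0.14). Wnt4, a ligand needed for ovary development, was called in no comparison, with means from 1226 ± 192 at pnd2 to 2001 ± 409 at gd12. Cyp17a1, an enzyme of androgen synthesis, was not called either and had its highest mean at gd16 (162 ± 32.3). Nanog and Amh stayed below the filter, with highest means of 72.48 ± 9.49 at gd12 and 11.54 ± 14.9 at gd11, and were not tested.

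**Figure D3:**
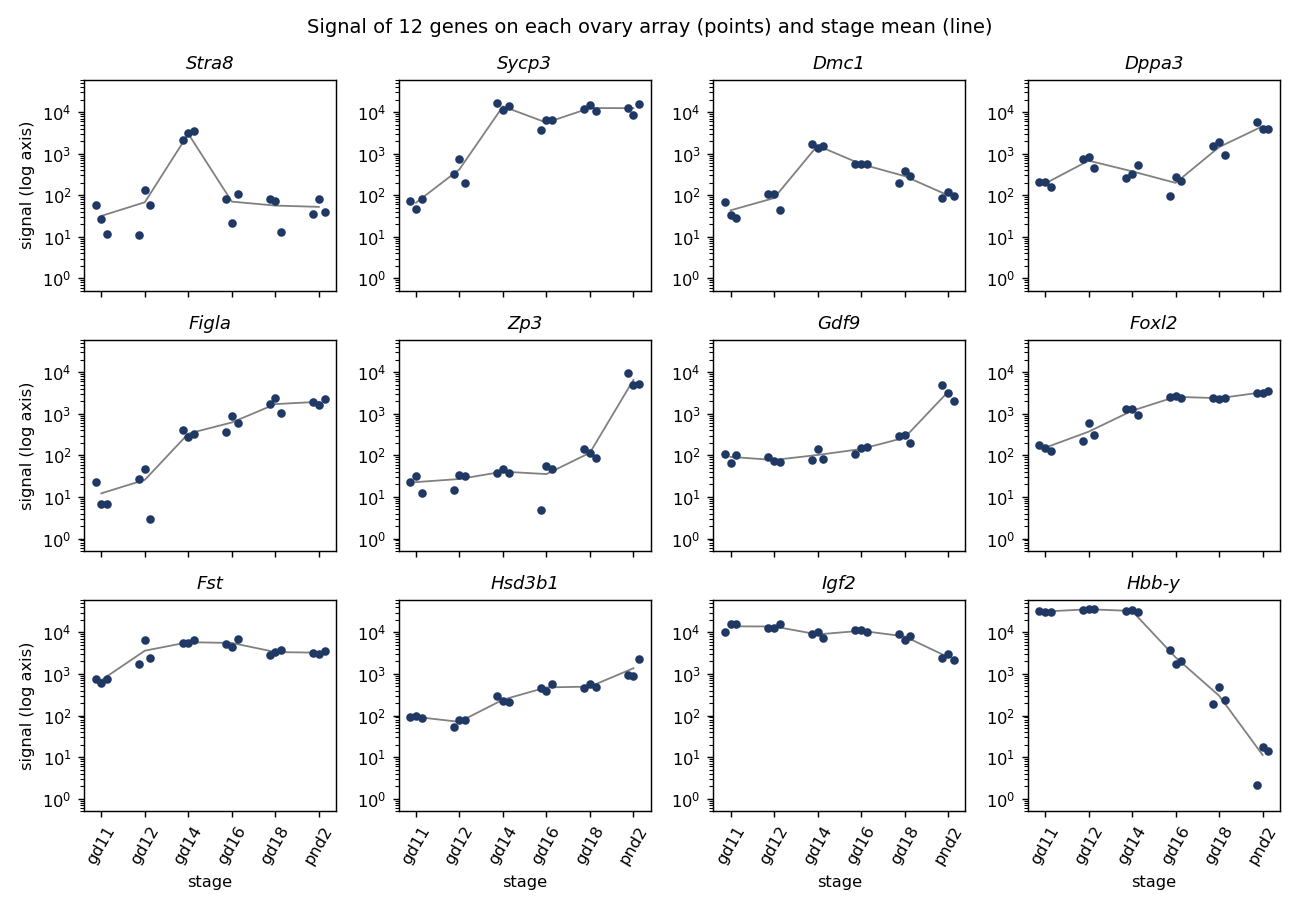
Signal (log axis) of 12 marker genes on each ovary array, by stage; points are arrays and the line joins the stage means. Stra8 is highest at gd14 (2990) and Zp3 at pnd2 (6569).

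Beside the whole-animal reference, for which no test was run, 2584 genes were at least 2-fold higher in the pnd2 ovary and 1707 at least 2-fold lower. These counts also asked that the 3 pnd2 arrays lie on the same side of the reference. Only genes that passed the filter on the ovary arrays were counted, so genes of the whole animal with low signal in the ovary were left out. The counts of both directions therefore cannot be weighed against each other. The 3 pnd2 arrays lay on the same side of the reference for 10453 of 12592 genes, an order that chance gives for 50% of genes. The highest log2 ratios were those of oocyte, germ cell and granulosa genes: Nlrp5 (8.72), Amhr2 (8.20), Nlrp4f (8.14), Nlrp14 (8.09), Padi6 (8.04), Sycp3 (7.53), Gtsf1 (7.52) and Zp3 (7.48). The lowest were those of the plasma proteins Afp (-9.73), Ttr (-9.05), Alb (-8.41) and Ambp (-8.28), the muscle genes Acta1 (-8.85), Myh8 (-8.15) and Myh3 (-8.03) and the liver enzyme Bhmt (-7.99). Median log2 ratios were 4.64 for the germ cell list, 4.62 for the oocyte list, 1.49 for the granulosa list and -3.35 for the nervous tissue list.

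Xist, which is transcribed from the inactive X of female cells, had a signal of 11306 to 18576 on 17 of the 18 ovary arrays and of 44.79 on that of gd16 sample 7, by the probe set with the highest signal. The other 2 Xist probe sets read 136.2 and 6.3 on that array and at least 6368.5 and 918 on the other ovary arrays. Of 2 probe sets of the Y-linked gene Eif2s3y, 1 read at most 26.3 on the ovary arrays (23.7 on that of gd16 sample 7) and 802.7 on the reference of both sexes. The other read 40.2 on gd16 sample 7, at most 33.1 on the other ovary arrays and 7.1 on the reference. For the Y-linked genes Uty and Kdm5d, the probe sets highest on the reference (125.3 and 131.5) read 13.5 and 4 on gd16 sample 7 and at most 44 and 29.6 on the other ovary arrays. A further Uty probe set read 22.4 on gd16 sample 7, at most 11.4 on the other ovary arrays and 50.7 on the reference.

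**Figure D4:**
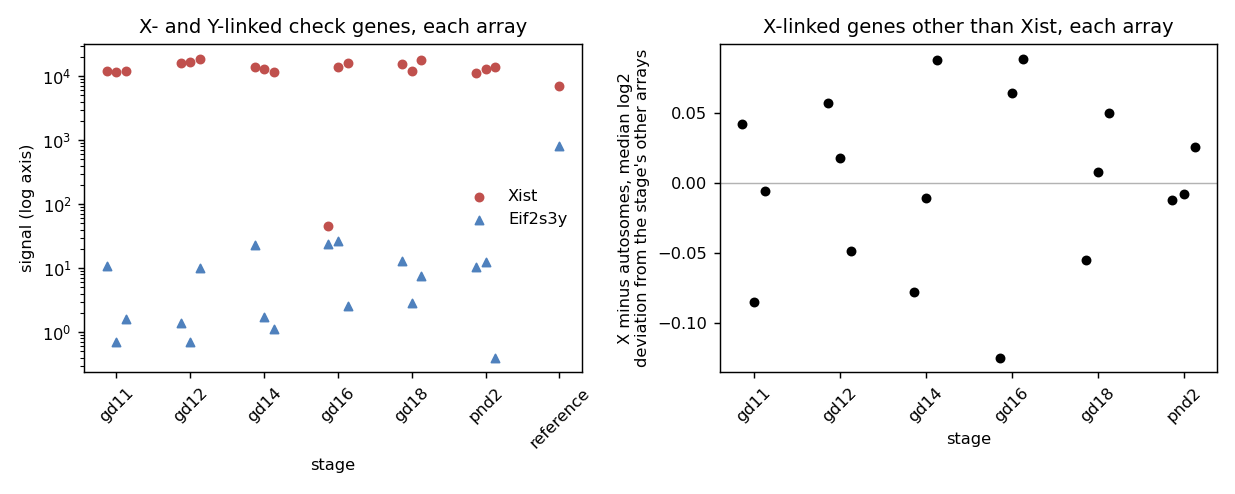
Signals of 1 probe set each of Xist and Eif2s3y (log axis) on each array, and for each ovary array the median log2 deviation of X-linked genes from the stage mates minus that of autosomal genes. The array of gd16 sample 7 has the lowest Xist signal (44.79) and the lowest difference (-0.125).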

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

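Every alternative reported in this part was fixed in advance. Of 379 changes of named genes, 256 kept their direction and their call under all alternatives in which the gene was tested. With the filter at the 75th percentile 333 kept the call and 1 lost it, and the others were not tested. Under at least 1 alternative 123 lost the call, of which 3 also reversed: Ctnnb1 at gd18 against gd16 (0.0374 after quantile normalization, adjusted p = 0.829), and Laptm5 (-0.0804, adjusted p = 0.78) and Mcl1 (-0.0706, adjusted p = 0.612) at gd16 against gd14 with the mean of all probe sets of a gene. The cause was not tested. With the filter at the 75th percentile, which tests fewer probe sets, pnd2 against gd11 had 7355 called probe sets (11089 in the report) and the F test 10897 (16599). A fit to only the arrays compared, with fewer degrees of freedom, called 533 at gd12 (1089) and 959 at gd18 (2003). An added threshold of 2-fold, stricter by construction, left 545, 1643, 1251, 530 and 1271 in the 5 steps in order and 4883 in pnd2 against gd11. With gd11 samples 18 and 19 averaged into 1, 687 were called at gd12. Gene lists called at gd16 numbered 3 with array quality weights and 3 with the mean of all probe sets (6 in the report), and the cause was not tested. With an estimated inter-gene correlation, which widens the null of each list, camera called 1 list at gd12 (10 with the preset correlation), 2 at gd14 (11), 0 at gd16 (6; 2 at an unadjusted p under 0.05), 1 at gd18 (4), 1 at pnd2 against gd18 (11) and 1 at pnd2 against gd11 (12). Without 1 array at a time, called probe sets ran from 339 to 894 at gd12, 2604 to 4209 at gd14, 2927 to 4450 at gd16, 1136 to 1989 at gd18, 1822 to 3340 at pnd2 against gd18 and 9634 to 9954 at pnd2 against gd11, and lists from 10 to 12, 8 to 15, 3 to 7, 3 to 6, 9 to 11 and 12 to 13. The F test ran from 15206 to 16405. The lowest counts were those without gd12 sample 14 (339), gd12 sample 15 (2604), gd14 sample 12 (2927), gd18 sample 4 (1136) and pnd2 sample 1 (1822). Quantile normalization and median scaling kept the counts within 1.5-fold but moved the balance of directions: at gd16 2559 were higher and 2406 lower as deposited, and 1862 and 2781 after median scaling. At pnd2 against gd11, 5922 and 5167 as deposited became 5142 and 6194 after median scaling and 5347 and 5731 after quantile normalization, and at pnd2 against gd18, 1744 and 1688 became 2028 and 1327 after median scaling. Signal over background was not measured. The filter is the median of all values, so the share of probe sets above it (47.85% to 54.17% per array) follows from its definition. The added constant shrinks the log2 changes of genes near the filter.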

Other observations

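The tests in this part were chosen after the results were seen, except the splits of the arrays and the test of fetal liver genes. The 4 tested genes of the X-linked Rhox homeobox cluster were called in the same direction at 3 of the 5 steps. Rhox5 rose from 1232 ± 128 at gd11 to 3998 ± 614 at gd12, Rhox6 from 328.3 ± 51.6 to 1155 ± 188, Rhox9 from 597.6 ± 110 to 2400 ± 739 and Rhox13 from 8.89 ± 4.84 to 148.6 ± 121 (3 of the 4 were called without gd11 sample 16, Rhox13 not). All 4 fell from gd14 to gd16, by log2 changes of -2.61 (Rhox5), -3.84 (Rhox6), -3.30 (Rhox9) and -1.89 (Rhox13), under both scalings and without gd16 sample 7. From gd18 to pnd2 all 4 fell as deposited, and 3 (not Rhox9) after quantile normalization or median scaling. Rhox13 went apart from the others at gd14, where it rose by 5.45 and they were not called (-0.20, -0.37 and -0.23), and in pnd2 against gd11, where it rose by 2.16 while Rhox5 (-2.49), Rhox6 (-3.02) and Rhox9 (-3.03) fell. Of 7 tested Nlrp genes, a family with maternal-effect members, all rose from gd18 to pnd2 under both scalings, from 1.94 ± 0.35 (Nlrp9a) to 5.94 ± 0.34 (Nlrp14). Nlrp9a and Nlrp4a passed the filter only through their pnd2 means (117.6 and 252.9), so their rise to pnd2 was largely set by the filter. Members with low signal at every stage were not tested. From gd16 to gd18, 4 rose (Nlrp5, Nlrp4f, Nlrp14 and Nlrp4b). At gd16 Nlrp5 rose by 1.84, and Nlrp14 (-1.17, not called without gd16 sample 7) and Nlrp4c (-1.90) fell. At gd12 Nlrp14 rose by 1.32.

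X-linked genes took a larger share of several changes than autosomal genes (exact Fisher tests, 12 in the family, 445 X-linked and 12102 autosomal genes). From gd11 to gd12, 42 X-linked genes (9.44%) and 371 autosomal genes (3.07%) were called higher (adjusted p = 8.14e-09, 3.17e-09 after quantile normalization, 6.72e-08 after median scaling and 4.96e-08 without gd11 sample 16). From gd12 to gd14 the shares called higher were 21.1% and 11.2% (adjusted p = 2.48e-08). At gd16 more X-linked genes were called lower (15.7% against 9.55%, adjusted p = 0.000179; 12.4% against 7.8%, adjusted p = 0.0028 without gd16 sample 7), and at pnd2 likewise (12.4% against 6.64%, adjusted p = 8.08e-05). The higher share at gd18 (8.54% against 4.82%, adjusted p = 0.00264) was not called without gd16 sample 7 (4.94% against 3.13%, adjusted p = 0.078). Genes of a chromosome are not independent, which this test does not take into account.

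The 3 probe sets of Bzw2 moved apart: 1 went from 324.7 ± 104 at gd11 to 37920 ± 3710 at pnd2, and the others from 727.7 ± 180 to 304.3 ± 33.7 and from 285.4 ± 36.4 to 112.1 ± 31.0. A direct comparison of gd18 with gd14 called 3383 probe sets, 1742 higher and 1641 lower at gd18, of which 1816 were also called at gd16 against gd14.

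The array of gd16 sample 7 had a Xist signal of 44.79, against 11306 to 18576 on the other 17 ovary arrays. A male animal under a female label was argued against by the Eif2s3y probe set that read 802.7 on the reference of both sexes, at 23.7 on this array and 26.3 on the highest other ovary array (a second read 40.2 on this array, the highest of the 18, but 7.1 on the reference). The Uty and Kdm5d probe sets highest on the reference (125.3 and 131.5) read 13.5 and 4 on this array. Another Uty probe set went the other way, at 22.4 on this array, at most 11.4 on other ovary arrays and 50.7 on the reference. For a defect of the array at the Xist probe sets, other X-linked genes were examined. Their median deviation from the stage mates minus that of autosomal genes was -0.125, against -0.0854 to 0.0884 on the other arrays. A permutation of genes gave p = 1e-04, the smallest it can give. It takes genes as independent and does not measure the spread between arrays. The value lay just outside the range of the other arrays, so a defect is not excluded. A candidate explanation is a single X chromosome in this animal: the median deviation of 6 genes that escape X inactivation was -0.522, with Pbdc1 at 1007 (2029 and 1515 on the stage mates), Kdm6a at 1254 (2035 and 1956) and Eif2s3x at 3188 (4292 and 4065). Ddx3x (10782 against 10599 and 12284) and Kdm5c (1406 against 1470 and 1869) were not lower than both mates by such a margin, and Mid1, at 120.6, was as low on gd14 sample 10 (119.7), so this stays a hypothesis.

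Genes of other tissues were high on some gd11 arrays. The median log2 level of the nervous tissue list, relative to each gene's mean over the ovary arrays, was 4.57 on gd11 sample 16 and 0.768 and 0.75 on the other gd11 arrays, a gap of 3.8, and 2.02 on gd12 sample 13 against -0.324 and 0.301 on the other gd12 arrays. Nervous tissue collected with gd11 sample 16 may account for its gap to the other gd11 arrays, the level of gd12 sample 13 shows that it was not the only array to stand apart, and no biological explanation was tested. For the 3 mesonephros genes called lower at gd14 (Wnt9b, Cdh16 and Lhx1), the gd11 array labelled gonad alone lay -0.495 from the mean of both arrays labelled with mesonephros, but over all 10 tested genes of the list it was the highest (0.605, against 0.491 and 0.579). Because only 1 array was labelled gonad alone and the direction turned with the genes taken, mesonephros collected with the gonad at gd11 and gd12 but not later cannot be told apart from a change within the ovary.

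At gd16, 978 probe sets were called in the steps from gd14 and to gd18 with opposite sign, 373 up then down and 605 down then up, whether or not they came back to the gd14 level, and 65 with the same sign. Both steps share the 3 gd16 arrays, whose noise favours opposite signs, and the step to gd18 had 2003 called probe sets and 1156 without gd16 sample 7. In simulated arrays with equal means at gd14, gd16 and gd18 and independent noise, the mean count over 20 draws was 0. That setting holds no real change between stages and no noise shared within an array, so it cannot give the part played by noise here. Another intensity scale of the gd16 arrays was argued against as the whole cause, since 1053 probe sets were called with opposite sign after quantile normalization. For the erythroid genes high at gd16, fetal liver tissue stays open: the median log2 change of its 10 genes from gd14 to gd16 was 0.6, and none of the 4 tested passed limma, with adjusted p from 0.144 (Alb, 286 at gd14 and 716 at gd16) to 0.934 (Ambp, 30.8 and 28.1), and Afp at 835 and 953. The median log2 level of the 6 erythroid genes other than embryonic globins was higher on each gd16 array (1.92, 1.56 and 1.05) than on any gd14 or gd18 array (highest 0.902), a gap of 0.152, but this restates the pattern, and a larger share of definitive red cells in the gd16 ovaries stays open, as does the change from pooled to not pooled samples at this step, which was not tested.

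Splits of the 6 arrays of a comparison into 3 and 3 number 10, too few for a share under 0.05. As many called probe sets as the real split came from 1 of 10 splits, the real one, in each comparison: 1089 at gd12 (highest other 2), 4355 at gd14 (1), 4965 at gd16 (1), 2003 at gd18 (4), 3432 at pnd2 against gd18 (0) and 11089 at pnd2 against gd11 (0). As many called gene lists came from 5 of 10 at gd12 (10, highest other 14), 4 at gd14 (11, other 13), 2 at gd16 (6, other 10), 5 at gd18 (4, other 11), 1 at pnd2 against gd18 (11, other 10) and 2 at pnd2 against gd11 (12, other 12). With the preset correlation, other splits called as many lists or more in 5 of the 6 comparisons. Every other split exchanged 1 array of each stage, so it kept part of the stage difference and put the rest into the spread. Neither the counts of lists nor those of probe sets in these splits therefore measure chance. For the F test, 1 of 100 splits of the 18 arrays, the real one, gave as many called probe sets (16599, highest other 553). This argues against no difference at all between the stages. The drawn splits mix stages, which widens the spread, so they do not give the share of the calls due to chance. Nor do they part stage from pooling or from the 3' to 5' ratios that moved with it.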
